A study of Mus musculus with 6 samples.

How the data were processed

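RNA-seq libraries were made from lineage-marked prostate epithelial cells of male mice of the lines labelled Nkx (CreER;EYFP) and Clu (CreER;tdTomato). Per the labels, mice were left intact or castrated at 8 weeks of age, tissue was taken 4 weeks later and digested, marker-positive cells were sorted into lysis buffer, and 2 ng of total RNA entered a stranded total RNA kit for low input. The labels give no sorting gate beyond the marker, no time of Cre induction and no sequencing batch. They also do not say whether replicates are separate animals.

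The authors deposited raw read counts per gene symbol, 1 column for each of the 6 libraries, in 24498 genes of which 4599 had no count. The unit was checked from the values, which are whole numbers whose column totals differ between libraries. Per the submitters' processing notes, FastQC 0.11.9, STAR 2.7.9a, Subread 2.0.1 with featureCounts and the mouse build GRCm39 were used. The annotation release, the strand setting, and the handling of reads with several alignments and of molecular identifiers are not given in the sources used here. Counts of near-identical copies (C1rb and C1s2, the Gsdmc, Svs, Sbp, Gsta and Ly6 genes, and keratin pseudogenes) are uncertain for that reason, as are those of genes that overlap on opposite strands. No symbol is a Gm number or ends in Rik, so such gene models are not analysed here. The annotation at hand is GENCODE M21 on an earlier build. It holds 23628 of the symbols, and no coordinates are given.

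Depth lay between 10220118 and 17412874 counts. After the TMM scaling given below, 1 count was 0.0561 to 0.0988 CPM. Intervals and floors cover counting error only. For a group without a count a floor of 3 counts over its 2 libraries was used, and with 1 to 3 counts a ratio with its 95% counting interval is given.

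Analyses ran in R 4.3.3. Genes were filtered with edgeR 4.0.16 (filterByExpr on the 3 groups, 13846 genes kept), scaled by TMM (factors from 0.945 to 1.04), and fitted with glmQLFit with a mean for each group over all 6 libraries, which leaves 3 residual degrees of freedom (prior degrees of freedom 4.86, biological coefficient of variation 33.7%). Each of the 3 comparisons was a two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment at an adjusted p under 0.05 and no fold minimum. Fold changes are log2 and positive when the first-named group is higher, and their SE comes from the model. CPM means are over the 2 libraries of a group with their SD. Replicate numbers were not treated as pairs, since the labels do not link them.

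The comparisons, the tests, 28 gene lists (cell types of the prostate and its surroundings, hormone response, stress, signalling and metabolism) and the rule for naming genes were chosen before the data were examined. The rule took, per comparison, the 8 called genes with the largest change in each direction with a mean of at least 10 CPM and no overlap between the groups' libraries, up to 4 members of each list, and Clu. Some genes that met it are not reported here. Genes outside it are said to be chosen after their values were seen. Lists with at least 5 tested members (26 of 28) were tested with edgeR's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera called 13, 13 and 14 lists in the order Nkx castrate against Nkx intact, Clu intact against Nkx intact, and Clu intact against Nkx castrate. With an estimated correlation 0 lists were called (6, 5 and 6 at an unadjusted p under 0.05), and fry, a rotation test of whether a list's own genes move on balance in a direction, called 8, 8 and 10. Several lists share members, and the leukocyte list shares class II genes with antigen presentation, which epithelial cells can also make.

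On simulated counts with 200 changed genes and this design (10 draws), 63.0%, 61.2% and 64.1% of 4-fold changes and 12.5%, 11.6% and 9.46% of 2-fold changes were called, in the same order of comparisons, and 10.2%, 9.17% and 8.82% of calls fell on unchanged genes. With groups of 2, no regrouping of libraries can test chance and no rule for outlying libraries applies. Alternatives were other scaling factors, leaving out the most abundant genes, other filters, DESeq2 1.42.0, limma-voom (limma 3.58.1), only the groups compared, the replicate number as a block, a 2-fold minimum, and leaving out each library.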

Results

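RNA was sequenced in bulk from lineage-marked epithelial cells sorted from the mouse prostate, a gland whose secretory luminal cells depend on androgen. In the mouse line labelled Nkx, cells were marked by an inducible Cre recombinase with a yellow fluorescent reporter. In the other mouse line the recombinase was driven by Clu, the gene of the secreted chaperone clusterin, with a red fluorescent reporter. The Nkx-marked cells came from intact males and from males castrated at 8 weeks of age and killed 4 weeks later, and the Clu-marked cells came from intact males of matched age. The 3 groups, Nkx intact, Nkx castrate and Clu intact, held 2 libraries each, named here by group and replicate number (Nkx intact 1). The labels do not say whether the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical. Counts assigned to genes totalled 10542213 and 10220118 in the Nkx intact libraries, 17412874 and 14326063 in the Nkx castrate libraries, and 11418079 and 10537941 in the Clu intact libraries. The number of genes with a count lay between 15045 and 15778 in 5 libraries and was 18516 in Nkx castrate 1. Libraries of the same group correlated at r = 0.956 (Nkx intact), 0.920 (Nkx castrate) and 0.970 (Clu intact) on log2 CPM across genes, which are not independent replicates. CPM are counts scaled to the library totals after adjustment by the TMM factors. The first principal component, with 42.4% of the variance, parted Clu intact from the Nkx groups, and the next, with 28.6%, parted Nkx intact from Nkx castrate.

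Ribosomal and marker RNA also varied by library. The 18S ribosomal RNA took 5.34% and 5.21% of counts in Nkx intact, 3.86% and 4.25% in Nkx castrate, and 2.25% and 2.91% in Clu intact. The mitochondrial ribosomal RNAs took 5.29%, 5.72%, 5.90%, 6.80%, 8.57% and 8.50% in the same order. Nkx castrate 1 held the most leukocyte and stromal marker RNA. Its 19 leukocyte markers summed to 806 CPM, against 169 CPM in Nkx castrate 2, 337 and 339 CPM in Nkx intact, and 80.2 and 82.1 CPM in Clu intact. Its 20 fibroblast and smooth muscle markers summed to 2696 CPM, against 607 CPM in Nkx castrate 2 and between 852 and 1042 CPM in the other 4 libraries. The 12 endothelial markers summed to 100.3 and 69.6 CPM in Nkx intact, 557 and 87.3 CPM in Nkx castrate, and 1235 and 510 CPM in Clu intact. The 20 basal markers summed to 6753 and 6888 CPM in Nkx intact, 6312 and 3985 CPM in Nkx castrate, and 4420 and 4306 CPM in Clu intact.

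The comparison of Nkx castrate with Nkx intact describes the state of Nkx-marked cells after castration. Genes of secreted prostate proteins fell. Tgm4, a transglutaminase of seminal fluid, averaged 9825 ± 2021 CPM (SD, n = 2) in Nkx intact and 3.03 ± 1.67 CPM (SD, n = 2) in Nkx castrate, a log2 fold change of -11.63 (SE 0.38). Pbsn, the gene of the androgen-dependent secretory protein probasin, fell from 6165 ± 1092 to 109 ± 4.39 CPM (log2 fold change -5.82, SE 0.22), and Msmb, another secreted protein of the prostate, fell 173-fold to 0.612 ± 0.389 CPM. Upk3a, a urothelial plaque protein, rose from 0.287 ± 0.406 to 171 ± 36.3 CPM (log2 fold change 9.15, SE 0.94), and Pigr, which carries polymeric immunoglobulin across epithelia, rose 15.9-fold to 1153 ± 292 CPM. Each of these means is over 2 libraries with its SD. The complement protease homologues C1rb and C1s2 fell 809-fold and 202-fold, although reads of these genes can be shared with near-identical copies. Among the largest increases were Slc34a2, a sodium-phosphate cotransporter (76.2-fold) and Sytl5, a vesicle-docking protein (35.5-fold). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.000111 for Tgm4 and for Pbsn, 0.000794 for Msmb, 0.000795 for Upk3a and 0.00207 for Pigr. Across 13846 tested genes, 556 were higher and 636 lower in Nkx castrate at an adjusted p under 0.05, of which 461 and 517 changed at least 2-fold, and 3262 genes had an unadjusted p under 0.05. Leaving out a library moved the fold of 10 of the 46 called genes named for this comparison over 1.5 times. The log2 fold change of Upk3a was 8.19 without Nkx intact 2 and 14.09 without Nkx intact 1, which leaves 0 counts in Nkx intact, that of Tgm4 -12.37 without Nkx castrate 1, that of C1s2 -10.13 without Nkx castrate 1 and -6.87 without Nkx castrate 2, that of Msmb -6.67 without Nkx intact 1, -6.84 without Nkx castrate 1 and -8.22 without Nkx castrate 2 and that of Slc34a2 5.29 without Nkx castrate 2. The counts of genes were 101 higher and 185 lower without Nkx intact 1, and 72 and 137 without Nkx intact 2. They were 1089 and 1323 without Nkx castrate 1, 1220 and 1164 without Nkx castrate 2, and 345 and 425 without Clu intact 1 and 338 and 410 without Clu intact 2.

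**Figure D1:**
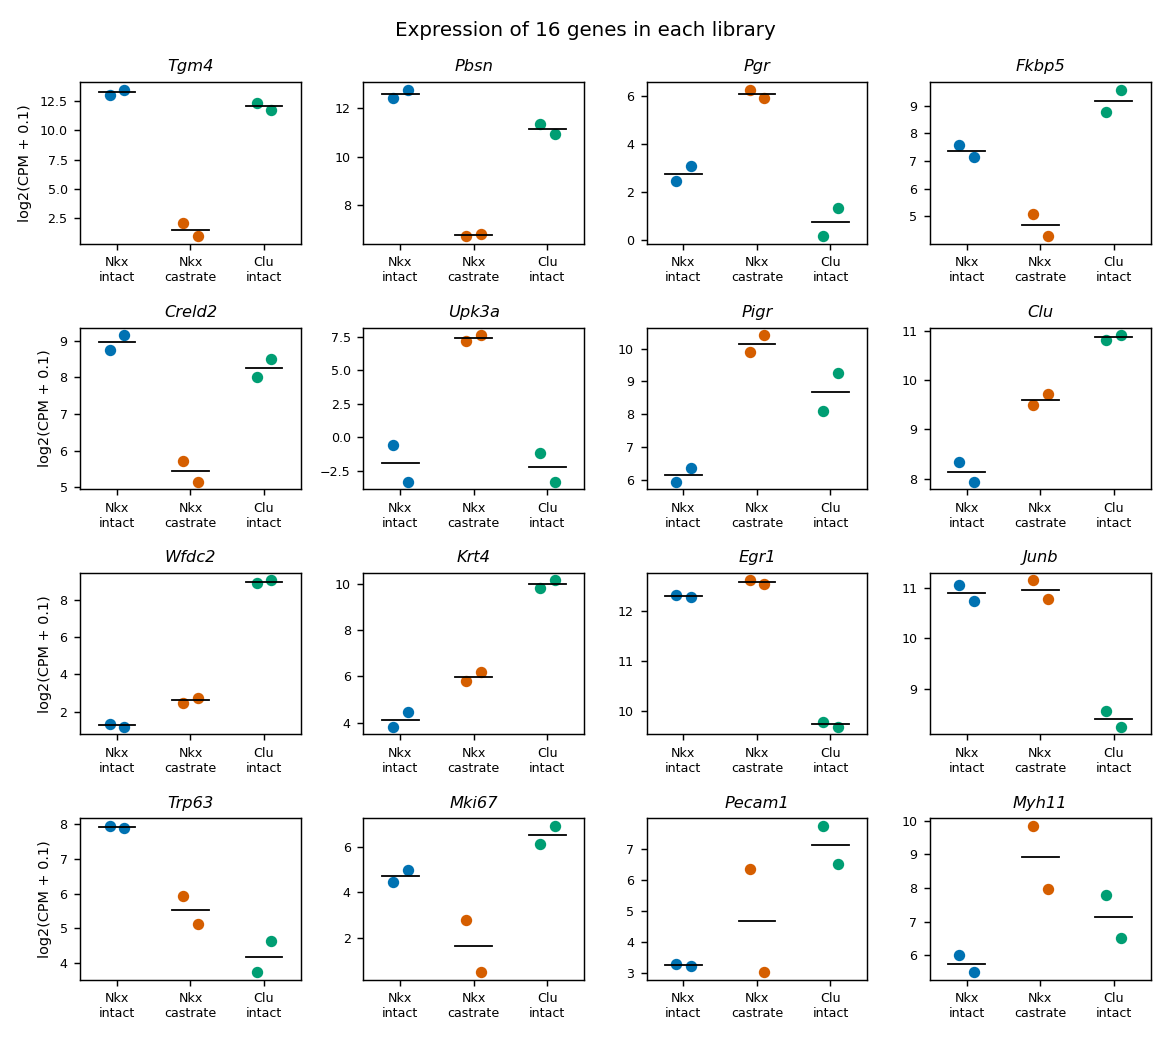
Each panel plots log2(CPM + 0.1) of 1 of 16 genes in the 6 libraries, with a point per library and a line at each group's mean. Tgm4 lay near 9825 CPM in Nkx intact and near 3.03 CPM in Nkx castrate, and Wfdc2 near 2.33 CPM in Nkx intact and near 499 CPM in Clu intact.

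Clu and Pgr, the gene of the progesterone receptor, rose with castration. Clu went from 284 ± 55.1 to 783 ± 86.5 CPM (SD, n = 2; log2 fold change 1.46, SE 0.20), and Pgr rose 10.1-fold. Of the 10 lineage genes and hormone receptors, 5 rose and 1 fell, or 5 and 3 when adjusted over the list alone, and the list did not pass in edgeR's camera (Benjamini-Hochberg adjusted p = 0.0744). For Clu and Pgr, edgeR's quasi-likelihood test gave Benjamini-Hochberg adjusted p-values of 0.00606 and 0.00353. Leaving out Nkx intact 2 ended the call of Clu (adjusted p = 0.0951, edgeR quasi-likelihood, Benjamini-Hochberg). The number of list members that rose was 2 without Nkx intact 1 and 1 without Nkx intact 2, and the number that fell was 0 without Nkx intact 2 and 2 without either Nkx castrate library.

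Secretory and protein-folding genes fell together. Of the 22 distal luminal secretory markers tested, 14 fell and 1 rose, or 16 and 1 when adjusted over the list alone. Man1a, a mannosidase of glycoprotein processing, fell from 1045 ± 162 to 136 ± 16 CPM (SD, n = 2; log2 fold change -2.94, SE 0.19). Of the 30 androgen response genes, 12 fell and 4 rose, or 13 and 7 when adjusted over the list alone, and Azgp1, a secreted zinc-binding glycoprotein, fell 20.9-fold. Of the 26 genes of protein folding and secretion in the endoplasmic reticulum, 17 fell and none rose, or 21 fell when adjusted over the list alone. Among them Creld2, a folding factor induced by endoplasmic reticulum stress, fell from 499 ± 97.5 to 43.8 ± 11.8 CPM (log2 fold change -3.51, SE 0.26), Pdia4, a disulphide isomerase, fell 5.34-fold, and Sdf2l1 fell 14.2-fold. Of the 22 xenobiotic and glutathione genes, 5 fell and 1 rose, with the same counts when adjusted over the list alone. Aldh1a1, a retinaldehyde dehydrogenase, fell from 302 ± 20.2 to 18.8 ± 3.54 CPM, Gsta3, a glutathione transferase with close copies, fell 16.9-fold (log2 fold change -3.31 without Nkx castrate 1 and -5.36 without Nkx castrate 2), and Gpx3, a secreted glutathione peroxidase, rose 11.6-fold. Slc30a2, a zinc transporter, fell 8.97-fold, and Igfbp5, a binding protein of insulin-like growth factors, fell 13.4-fold. The secretory markers and the androgen response genes had adjusted p = 9.18e-34 and 5.64e-08 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.0642 and 0.0642 with an estimated correlation. The folding genes and the xenobiotic genes had adjusted p = 1.03e-28 and 0.00431 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.173 and 0.173 with an estimated correlation. Androgen response genes that fell numbered 5 without Nkx intact 2. Those that rose numbered 0 without either Nkx intact library and 7 without either Nkx castrate library. Secretory markers that rose numbered 0 without either Nkx intact library or either Clu intact library and 2 without Nkx castrate 1, and folding genes that fell numbered 8 without Nkx intact 2. Xenobiotic genes that fell numbered 3 without Nkx intact 1 and 2 without Nkx intact 2, and those that rose 0 without either Nkx intact library and 2 without either Nkx castrate library. Gpx3 was no longer called without either Nkx intact library, with an adjusted p of up to 0.0984 (edgeR quasi-likelihood, Benjamini-Hochberg).

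Some basal, cell cycle and seminal vesicle genes also fell. Of the 20 basal epithelial markers, 7 fell and none rose, or 9 fell when adjusted over the list alone. Trp63, the transcription factor of basal cells, fell from 244 ± 7.95 to 48.1 ± 18.9 CPM (SD, n = 2; log2 fold change -2.34, SE 0.34). Lamb3, a laminin chain of the basement membrane, fell 3.26-fold. Of the 25 cell cycle genes, 3 fell and none rose, or 4 fell and 1 rose when adjusted over the list alone. The proliferation marker Mki67 fell 6.32-fold to 4.14 ± 3.98 CPM and Rrm2, a ribonucleotide reductase subunit, 5.26-fold. Of the 6 seminal vesicle secretion genes tested, 4 fell, or 6 when adjusted over the list alone. Svs5, a seminal vesicle secretory protein, went from 27.1 ± 13.1 CPM to 0 counts, at least 281-fold lower against a floor of 3 counts over the group's 2 libraries. The basal markers and the cell cycle genes had adjusted p = 2.42e-05 and 0.00497 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.493 and 0.555 with an estimated correlation. The seminal vesicle genes had adjusted p = 3.03e-09 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.173 with an estimated correlation. The number of basal markers that fell was 0 without either Nkx intact library and 16 without Nkx castrate 1. It was 1 without Nkx intact 1, 0 without Nkx intact 2 and 9 without Nkx castrate 1 for the cell cycle genes and 1 without either Nkx intact library for the seminal vesicle genes. Trp63, Lamb3, Mki67 and Svs5 lost their calls without either Nkx intact library, with adjusted p of up to 0.0754, 0.0785, 0.235 and 0.148 (edgeR quasi-likelihood, Benjamini-Hochberg). The log2 fold change of Mki67 was -4.32 without Nkx castrate 1 and -1.95 without Nkx castrate 2. Its call was also lost without Clu intact 2, and that of Rrm2 without Nkx intact 2 (Benjamini-Hochberg adjusted p = 0.0706 in the edgeR quasi-likelihood test).

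Markers of proximal luminal cells, which lie near the urethra, and of the urothelium rose. Of the 24 proximal luminal markers, 12 rose and 3 fell, or 14 and 3 when adjusted over the list alone. Atp10b, a lipid flippase, rose from 4.08 ± 0.0925 to 28.1 ± 0.0738 CPM (SD, n = 2; log2 fold change 2.78, SE 0.22), Krt19, a simple-epithelial keratin, rose 4.34-fold, and Cp, the gene of ceruloplasmin, fell 3.69-fold. Of the 13 urothelial markers, 7 rose and none fell, or 8 rose when adjusted over the list alone. Sprr1a, a cornified-envelope precursor, rose 7.39-fold to 878 ± 144 CPM and Upk1a, another uroplakin, 7.88-fold (log2 fold change 2.30 without Nkx castrate 2). The proximal markers and the urothelial markers had adjusted p = 1.64e-05 and 2.72e-15 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.173 and 0.0642 with an estimated correlation. The number of proximal markers that rose was 3 without either Nkx intact library, and the number that fell was 1 without either Nkx intact library and 6 without Nkx castrate 1. The urothelial markers that rose numbered 3 without Nkx intact 1 and 4 without Nkx intact 2. Krt19 and Upk1a were no longer called without either Nkx intact library, with adjusted p of up to 0.0634 and 0.0654 (edgeR quasi-likelihood, Benjamini-Hochberg).

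In camera some immune lists passed upward only at preset correlation. Antigen presentation, endothelial, stromal and leukocyte tests changed without Nkx castrate 1, the higher of its group in leukocyte and endothelial marker RNA. Of the 24 JAK-STAT pathway genes, 4 rose and 1 fell, or 7 and 1 when adjusted over the list alone. Stat3 rose from 196 ± 3.6 to 446 ± 66.9 CPM (SD, n = 2; log2 fold change 1.19, SE 0.18), and the interferon gamma receptor Ifngr1 fell 2.27-fold. Of the 19 antigen presentation genes, 3 rose and 1 fell, or 7 and 1 when adjusted over the list alone. The gene that fell was B2m, the light chain of class I molecules (3.21-fold). Of the 29 interferon-stimulated genes, Parp14 rose 2.24-fold and the chemokine gene Cxcl10 fell 5.17-fold, with the same counts of 1 and 1 when adjusted over the list alone. Of the 20 fibroblast and smooth muscle markers, 5 rose and none fell, or 7 rose and 1 fell when adjusted over the list alone. The smooth muscle genes Myh11 and Acta2 rose from 54.8 ± 14 to 586 ± 476 CPM and from 20.8 ± 10.7 to 216 ± 166 CPM. Their log2 fold changes of 3.42 and 3.37 became 2.19 without Nkx castrate 1 and 4.07 without Nkx castrate 2 for Myh11, and 4.01 without Nkx intact 1, 2.24 without Nkx castrate 1 and 3.99 without Nkx castrate 2 for Acta2. No member of the 12 endothelial or 19 leukocyte markers was called by edgeR, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 8 endothelial markers higher, and 1 leukocyte marker higher and 1 lower. DESeq2 called 2 endothelial markers higher and 1 leukocyte marker in each direction, and limma-voom called 0 of either list. The endothelial genes Pecam1 (9.47 ± 0.404 CPM in Nkx intact and 44.4 ± 51.5 CPM in Nkx castrate) and Vwf (11.2 ± 3.59 and 42.3 ± 45.2 CPM) and the class II chain Cd74 (95 ± 9.03 and 169 ± 141 CPM) had log2 fold changes of 2.23, 1.92 and 0.83, none called. These were -0.25, -0.13 and -0.45 without Nkx castrate 1. Without Nkx castrate 2 Pecam1 was at 3.085 and Vwf at 2.715, and all were called. The JAK-STAT list, called upward, had adjusted p = 0.00431 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.173 with an estimated correlation. Antigen presentation, also upward, had adjusted p = 0.00661 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.414 with an estimated correlation. The interferon list, upward, and the endothelial list, upward, had adjusted p = 0.000798 and 0.00496 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.555 and 0.643 with an estimated correlation. The stromal (adjusted p = 0.202) and leukocyte (adjusted p = 0.81) lists did not pass (edgeR camera, Benjamini-Hochberg). Without Nkx castrate 1, antigen presentation and the endothelial list no longer passed in camera. The stromal and leukocyte lists passed without either castrate library, but with opposite leanings. Their called members were mostly lower without Nkx castrate 1 and mostly higher without Nkx castrate 2. The stromal markers that rose numbered 0 without either Nkx intact library and 12 without Nkx castrate 2, those that fell 10 without Nkx castrate 1 and 3 without Nkx castrate 2. Endothelial markers called higher numbered 11 without Nkx castrate 2. Leukocyte markers called lower numbered 5 without Nkx castrate 1 and 1 without Nkx castrate 2 and higher 6 without Nkx castrate 2. The JAK-STAT genes that rose numbered 0 without either Nkx intact library and 7 without either Nkx castrate library and those that fell 0 without either Nkx intact library. The antigen presentation genes that rose numbered 0 without either Nkx intact library, 6 without Nkx castrate 1, 7 without Nkx castrate 2 and 1 without either Clu intact library and those that fell 0 without either Nkx intact library. The interferon genes that rose numbered 0 without either Nkx intact library, 8 without Nkx castrate 1 and 6 without Nkx castrate 2 and those that fell 0 without either Nkx intact library. The calls of Stat3, Ifngr1, B2m, Parp14, Cxcl10, Myh11 and Acta2 were lost without either Nkx intact library, with adjusted p of up to 0.113, 0.0951, 0.0944, 0.22, 0.0987, 0.199 and 0.207 (edgeR quasi-likelihood, Benjamini-Hochberg).

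The other lists were not called by camera in this comparison. Of the 26 immediate early and dissociation genes 1 rose and 3 fell (2 and 5 when adjusted over the list alone), with Ccn1, a matricellular protein, 2.6-fold lower. Of the 12 AP-1 genes 1 rose (3 higher and 1 lower when adjusted over the list alone). Gadd45a, a growth arrest gene, rose 9-fold from 30.9 ± 4.82 to 278 ± 129.6 CPM (SD, n = 2), in an apoptosis and regression list of 23 with 2 higher and 1 lower, the same when adjusted over the list alone. Odc1, the ornithine decarboxylase of polyamine synthesis, fell 3.49-fold, 1 of 2 that fell beside 1 that rose among 20 polyamine and citrate genes, the same when adjusted over the list alone. Fkbp5, a cochaperone induced by steroid receptors, fell 6.33-fold from 168 ± 35.2 to 26.4 ± 10.1 CPM, the 1 called gene of 12 glucocorticoid-induced genes (2 lower when adjusted over the list alone). Higher and lower members numbered 3 and 0 of 25 NF-kB genes (5 and 1 when adjusted over the list alone) and 4 and 3 of 26 Wnt genes (5 and 4 when adjusted over the list alone). They numbered 1 and 2 of 15 complement and defence genes (2 and 2 when adjusted over the list alone). None of 14 mitochondrially encoded genes, 4 ionocyte or neuroendocrine markers and 4 red blood cell genes was called by edgeR. At an unadjusted p under 0.05 there was 1 ionocyte or neuroendocrine marker, which DESeq2 also called higher and limma-voom did not, and 0 of the others by any of these counts. For the mitochondrial and cholesterol lists the median or mean had another sign than the camera test. Leaving out a library brought adjusted p under the threshold (edgeR camera, Benjamini-Hochberg) at 0.0339 without Nkx castrate 1 for the lineage and receptor list, 0.0445 without Nkx castrate 2 for AP-1 and 0.01 without Nkx castrate 2 for NF-kB. The complement list also passed without either castrate library, its called members mostly lower without Nkx castrate 1 and mostly higher without Nkx castrate 2. The polyamine list passed without Nkx intact 1 or Nkx castrate 2 and the glucocorticoid list without Nkx intact 2. Genes that rose numbered 0 without either Nkx intact library or either Clu intact library, 2 without Nkx castrate 1 and 3 without Nkx castrate 2 in the AP-1 list. In the NF-kB list they numbered 0 without either Nkx intact library, 5 without Nkx castrate 1 and 7 without Nkx castrate 2, in the Wnt list 0 without either Nkx intact library and 7 without Nkx castrate 1 and in the apoptosis list 1 without either Nkx intact library and 5 without Nkx castrate 2. They numbered 0 without either Nkx intact library or either Clu intact library and 2 without either Nkx castrate library in the immediate early list, 4 without Nkx castrate 2 in the complement list and 0 without either Nkx intact library and 2 without Nkx castrate 1 in the polyamine list. Genes that fell numbered 0 without Nkx intact 1, 1 without Nkx intact 2, 8 without Nkx castrate 1 and 5 without Nkx castrate 2 in the immediate early list and 0 without either Nkx intact library, 8 without Nkx castrate 1, 5 without Nkx castrate 2 and 1 without either Clu intact library in the Wnt list. In the complement list they numbered 0 without either Nkx intact library and 4 without Nkx castrate 1, and in the apoptosis list 4 without Nkx castrate 1. In the polyamine list they numbered 1 without Nkx intact 2, and in the glucocorticoid list 0 without Nkx intact 1, 3 without Nkx castrate 1 and 2 without Nkx castrate 2 or either Clu intact library. Ccn1 lost its call without either Nkx intact library (adjusted p up to 0.124), Odc1 without Nkx intact 2 (0.0743) and Fkbp5 without Nkx intact 1 (0.0514) (edgeR quasi-likelihood, Benjamini-Hochberg).

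**Figure D2:**
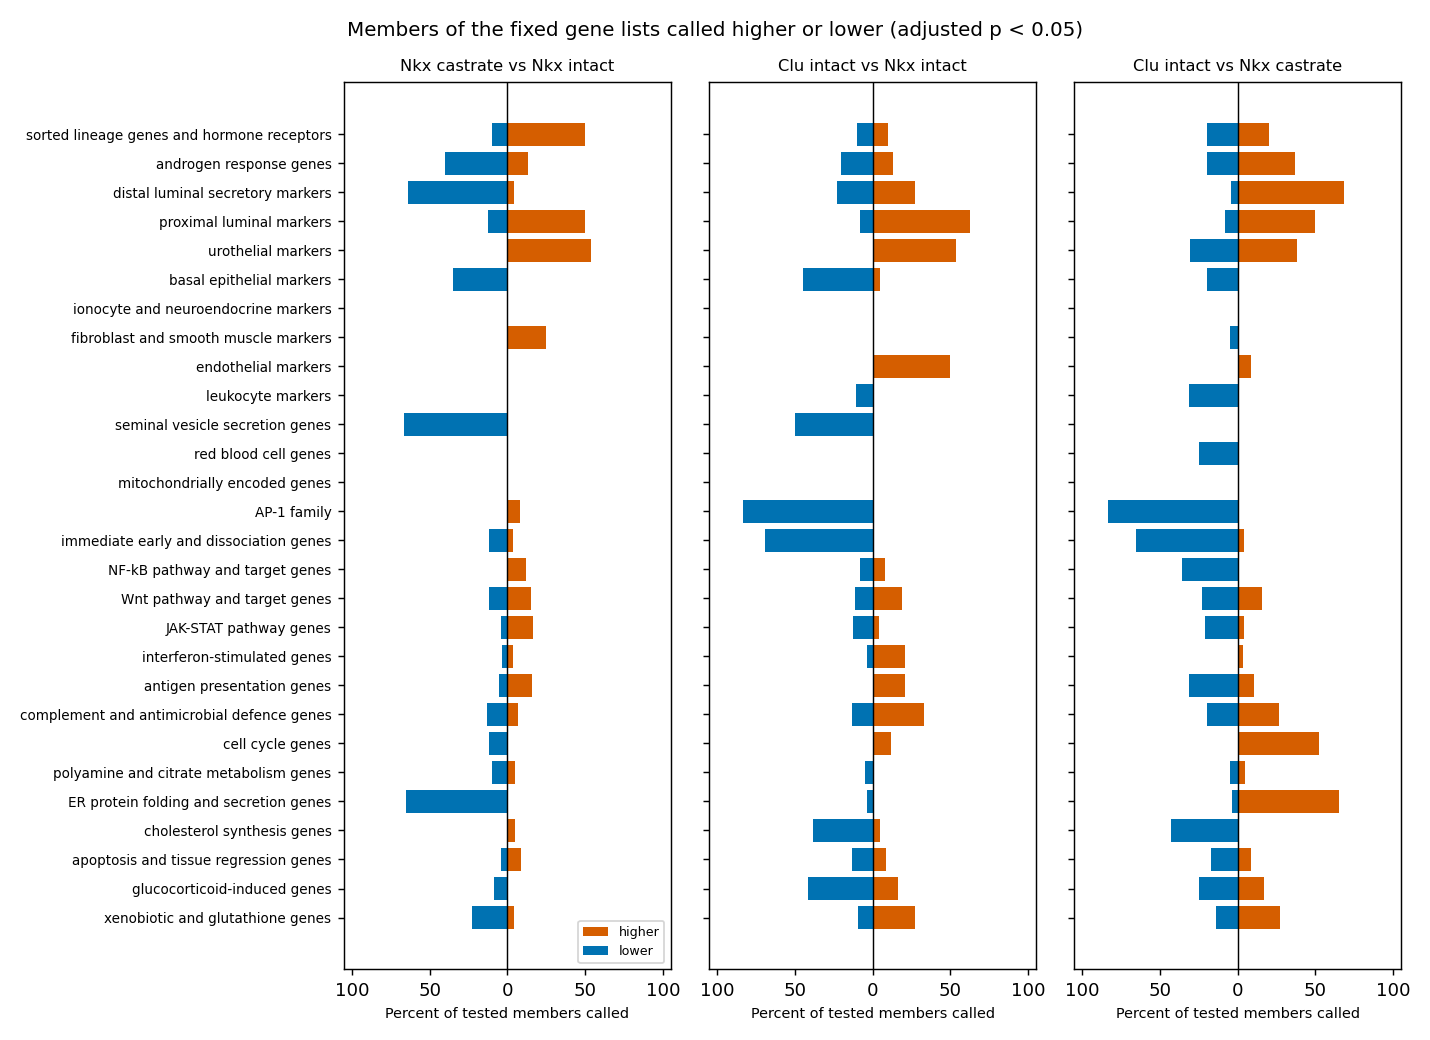
Bars give the percent of each list's tested members called higher (orange, right) or lower (blue, left) at an adjusted p under 0.05 in each of the 3 comparisons. Of 22 distal luminal secretory markers 14 were lower in Nkx castrate than in Nkx intact, and of 26 immediate early and dissociation genes 18 were lower in Clu intact than in Nkx intact.

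The comparison of Clu intact with Nkx intact sets the marked populations of intact males side by side, with mouse line and reporter differing along with the population. Proximal luminal and urothelial genes were higher in Clu intact. Wfdc2, a secreted whey acidic protein family member, averaged 499 ± 33.3 CPM (SD, n = 2) in Clu intact and 2.33 ± 0.222 CPM (SD, n = 2) in Nkx intact, a log2 fold change of 7.74 (SE 0.22). Krt4, a keratin of stratified and proximal luminal epithelium, was at 1011 ± 159 and 17.8 ± 5.56 CPM (log2 fold change 5.83, SE 0.26), and Ppp1r1b, a phosphatase inhibitor, was 161-fold higher. Of the 24 proximal luminal markers, 15 were higher and 2 lower, or 19 and 2 when adjusted over the list alone, with the glutathione transferase Gsta4 37.1-fold and Atp10b 22.2-fold higher. Of the 13 urothelial markers, 7 were higher and none lower, or 8 and 1 when adjusted over the list alone. These included Evpl, the cornified-envelope protein envoplakin (5.74-fold), and the gasdermin Gsdmc2 (60.0-fold), whose reads could be shared with near-identical copies. Clca1, a secreted protein of mucous epithelia, had 0 counts in Nkx intact and 82.6 ± 7.36 CPM in Clu intact, at least 569-fold higher, and Pglyrp1, a peptidoglycan-binding defence protein, was 192-fold higher. Azgp1 was 33-fold and Fmod, the matrix protein fibromodulin, 32.9-fold lower in Clu intact. Camk2b, a calmodulin-dependent kinase, averaged 73.5 ± 26.2 CPM in Nkx intact with 0 counts in Clu intact, at least 553-fold lower. For Wfdc2, Krt4, Clca1 and Azgp1, edgeR's quasi-likelihood test gave Benjamini-Hochberg adjusted p-values of 1.73e-05, 0.000199, 0.000414 and 0.000456. Of 13846 tested genes, 871 were higher and 692 lower in Clu intact at an adjusted p under 0.05, of which 738 and 567 differed at least 2-fold, and 3634 genes had an unadjusted p under 0.05. The proximal markers and the urothelial markers had adjusted p = 5.47e-39 and 5.97e-12 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.0709 and 0.0709 with an estimated correlation. Leaving out a library moved the fold of 10 of the 48 called genes named for this comparison over 1.5 times, such as Pglyrp1 (log2 fold change 6.92 without Nkx intact 1 and 8.90 without Nkx intact 2), Azgp1 (-5.71 without Clu intact 1) and Fmod (-5.95 without Clu intact 1). The counts of genes were 247 higher and 157 lower without Nkx intact 1 and 214 and 177 without Nkx intact 2. They were 1790 and 1561 without Nkx castrate 1, 1728 and 1525 without Nkx castrate 2, 353 and 218 without Clu intact 1, and 315 and 180 without Clu intact 2. The number of proximal markers lower was 1 without either Nkx intact library or either Clu intact library. The urothelial markers higher numbered 3 without Nkx intact 1 and 4 without Nkx intact 2 and lower 1 without either Nkx castrate library.

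Clu was 6.58-fold higher in Clu intact, at 1871 ± 89.5 against 284 ± 55.1 CPM (SD, n = 2; log2 fold change 2.72, SE 0.20), in the line whose Cre is driven by that gene. Of the 10 lineage genes and receptors, 1 was higher and 1 lower, or 2 and 2 when adjusted over the list alone. Secretory genes went both ways. Of the 22 distal luminal secretory markers, 6 were higher and 5 lower (7 and 7 when adjusted over the list alone). Of the 30 androgen response genes, 4 were higher and 6 lower (7 and 8 when adjusted over the list alone). Bace2, an aspartyl protease, was 13.3-fold higher, the glycosyltransferase gene Abo 12.4-fold higher and the transporter Abcc4 3.79-fold higher, whereas Pbsn was 2.69-fold lower. For Clu and Pbsn, edgeR's quasi-likelihood test gave Benjamini-Hochberg adjusted p-values of 0.000512 and 0.00748. The lineage (adjusted p = 0.896), secretory (0.74) and androgen response (0.521) lists did not pass (edgeR camera, Benjamini-Hochberg), and in all of them the median or mean had another sign than the test. Without Nkx intact 2 or Clu intact 2 the call of Pbsn was lost (adjusted p up to 0.0809, edgeR quasi-likelihood, Benjamini-Hochberg). Secretory markers higher numbered 2 without either Nkx intact library and 3 without Clu intact 2, and lower 2 without Nkx intact 1, 1 without Nkx intact 2, 9 without either Nkx castrate library and 3 without Clu intact 2. Androgen response genes higher numbered 1 without either Nkx intact library or Clu intact 2, 7 without either Nkx castrate library and 2 without Clu intact 1, and lower 3 without Nkx intact 1 or Clu intact 1, 2 without Nkx intact 2 and 1 without Clu intact 2. Lineage genes higher numbered 2 without either Nkx castrate library, and lower 0 without either Nkx intact library or Clu intact 1 and 3 without either Nkx castrate library.

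Immediate early genes and AP-1 factors were lower in Clu intact. Egr1, an immediate early transcription factor, averaged 856 ± 45.7 CPM in Clu intact and 5029 ± 104 CPM in Nkx intact (SD, n = 2; log2 fold change -2.56, SE 0.18). Junb, an AP-1 factor, was at 342 ± 52.5 and 1925 ± 292 CPM (log2 fold change -2.49, SE 0.22). Of the 26 immediate early and dissociation genes, 18 were lower and none higher, or 20 lower when adjusted over the list alone, with the nuclear receptor Nr4a1 6.63-fold, the antiproliferative gene Btg2 6.99-fold and Egr2 8.83-fold lower. Of the 12 AP-1 genes, 10 were lower, the same number when adjusted over the list alone, with Atf3 4.98-fold and Jun 3.79-fold lower. Of the 12 glucocorticoid-induced genes, 5 were lower and 2 higher, or 8 and 2 when adjusted over the list alone, with the clock gene Per1 5.52-fold lower and the sulphotransferase Sult1a1 10.6-fold higher. The summed immediate early list stood at 39720 and 36510 CPM in Nkx intact, 38500 and 37290 CPM in Nkx castrate, and 12160 and 11940 CPM in Clu intact. For Egr1 and Junb, edgeR's quasi-likelihood test gave Benjamini-Hochberg adjusted p-values of 0.000436 and 0.000904. The immediate early list and the AP-1 family had adjusted p = 8.98e-32 and 1.54e-13 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.0709 and 0.195 with an estimated correlation. The glucocorticoid list had adjusted p = 0.000667 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.219 with an estimated correlation. The number of immediate early genes lower was 11 without Clu intact 2, and that of AP-1 genes 4 without Nkx intact 1 or Clu intact 2 and 5 without Nkx intact 2. Glucocorticoid-induced genes lower numbered 1 without Nkx intact 1, 3 without Nkx intact 2 or Clu intact 2, 8 without either Nkx castrate library and 2 without Clu intact 1, and higher 0 without either Nkx intact library or Clu intact 2 and 1 without Clu intact 1. Sult1a1 lost its call without any of the Nkx intact or Clu intact libraries (adjusted p up to 0.108 (edgeR quasi-likelihood, Benjamini-Hochberg)).

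Markers of other cell types differed between the populations as well. Basal markers were lower in Clu intact, 9 of 20 with 1 higher, or 13 and 1 when adjusted over the list alone. Trp63 was at 18.9 ± 8.12 CPM in Clu intact and 244 ± 7.95 CPM in Nkx intact (SD, n = 2; log2 fold change -3.69, SE 0.34), the Notch ligand Jag2 was 5.5-fold and Dlk2 9.49-fold lower. Of the 12 endothelial markers, 6 were higher and none lower, or 11 higher when adjusted over the list alone, with Vwf at 183 ± 92.4 against 11.2 ± 3.59 CPM and the tight junction gene Cldn5 at 34.9 ± 21.1 against 0.239 ± 0.338 CPM. Of the 19 leukocyte markers, 2 were lower, or 8 when adjusted over the list alone, the lysozyme gene Lyz2 11.3-fold and the complement gene C1qa 8.33-fold. Of the 6 seminal vesicle genes, 3 were lower, or 5 when adjusted over the list alone, with Svs4 at 0.338 ± 0.477 against 72.1 ± 24 CPM. None of the 20 stromal markers, 14 mitochondrially encoded genes, 4 ionocyte or neuroendocrine markers or 4 red blood cell genes was called by edgeR. At an unadjusted p under 0.05 there were 3 stromal markers higher and 1 lower, 5 mitochondrial genes higher and 1 ionocyte or neuroendocrine marker lower. DESeq2 called 2 stromal and 5 mitochondrial genes higher, and limma-voom 2 mitochondrial genes. Endothelial markers higher numbered 9 with DESeq2 and 0 with limma-voom, and leukocyte markers lower 8 and 0. The mitochondrial ribosomal RNA mt-Rnr1 had a log2 fold change of 0.61 (SE 0.20) and was called without either castrate library. For Trp63, Vwf, Lyz2 and mt-Rnr1, edgeR's quasi-likelihood test gave Benjamini-Hochberg adjusted p-values of 0.00127, 0.0228, 0.0326 and 0.0888, the last of which fell to 0.000332 without a castrate library. The basal markers and the endothelial markers had adjusted p = 7.95e-08 and 6.86e-07 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.376 and 0.521 with an estimated correlation. The leukocyte markers and the seminal vesicle genes had adjusted p = 2.78e-05 and 7.00e-07 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.62 and 0.261 with an estimated correlation. Basal markers lower numbered 4 without either Nkx intact library and 5 without Clu intact 2, and higher 0 without either Nkx intact library or either Clu intact library, 3 without Nkx castrate 1 and 2 without Nkx castrate 2. Endothelial markers higher numbered 1 without Nkx intact 1 or Clu intact 1, 0 without Nkx intact 2 and 11 without either Nkx castrate library, and leukocyte markers lower 0 without either Nkx intact library or either Clu intact library, 10 without Nkx castrate 1 and 11 without Nkx castrate 2. Stromal markers higher numbered 5 without Nkx castrate 1 and 8 without Nkx castrate 2 and lower 1 without either Nkx castrate library. Mitochondrial genes higher numbered 6 without either Nkx castrate library and seminal vesicle genes lower 1 without either Nkx intact library or Clu intact 2 and 6 without Nkx castrate 1. The log2 fold change of Svs4 was -7.64, and -6.70 without Clu intact 2 and -12.82 without Clu intact 1, which leaves 0 counts. That of Vwf was 4.02, and 3.40 without Clu intact 1, and that of Cldn5 7.11, and 11.82 without Nkx intact 1, 6.16 without Nkx intact 2 and 6.33 without Clu intact 1 (0 counts left without Nkx intact 1). Cldn5 was no longer called without Nkx intact 2 (adjusted p = 0.0511), Vwf without Clu intact 1 or either Nkx intact library (up to 0.193; edgeR quasi-likelihood, Benjamini-Hochberg). Lyz2 and C1qa were no longer called without any of the Nkx intact or Clu intact libraries (adjusted p up to 0.169 and 0.153, edgeR quasi-likelihood, Benjamini-Hochberg).

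The xenobiotic, cholesterol synthesis, interferon and cell cycle lists also passed. Of the 22 xenobiotic and glutathione genes, 6 were higher and 2 lower, or 7 and 3 when adjusted over the list alone. The carbonyl reductase Cbr2 was at 776 ± 56.2 against 98 ± 6.62 CPM (SD, n = 2; log2 fold change 2.98, SE 0.16), with Cyp2f2 5.83-fold and Gsta3 10.8-fold higher. Of the 21 cholesterol synthesis genes, 8 were lower and 1 higher, or 11 and 1 when adjusted over the list alone, with the sterol oxidase Msmo1 3.37-fold lower. Of the 29 interferon-stimulated genes, 6 were higher and 1 lower, or 12 and 1 when adjusted over the list alone, with Parp14 3.14-fold higher and Cxcl10 7.83-fold lower (log2 fold change -3.66 without Clu intact 2). Of the 25 cell cycle genes 3 were higher, the same number when adjusted over the list alone, with the replication helicase subunit Mcm6 4.06-fold higher (log2 fold change 2.98 without Nkx intact 1). Of the 26 endoplasmic reticulum genes edgeR called 1, the stress-induced transcription factor Atf4 (2.82-fold lower, the same when adjusted over the list alone), DESeq2 3 lower and limma-voom 2 lower, and with edgeR it was 4 without either Nkx castrate library and 2 without Clu intact 2. The chaperone Hspa5 had a log2 fold change of -0.53 (SE 0.31), which did not pass. Higher and lower members numbered 5 and 2 of 15 complement and defence genes (8 and 4 when adjusted over the list alone), with the lipopolysaccharide-binding protein gene Lbp 7.04-fold and Pigr 6.12-fold higher (log2 fold change 1.95 without Clu intact 2). They numbered 5 and 3 of 26 Wnt genes (6 and 4 when adjusted over the list alone), with Wnt4 5.75-fold and Cd44 4.17-fold higher. The xenobiotic genes and the cholesterol synthesis genes had adjusted p = 0.00226 and 0.000283 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.219 and 0.366 with an estimated correlation. The interferon genes and the cell cycle genes had adjusted p = 5.46e-05 and 0.00137 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.537 and 0.537 with an estimated correlation. The xenobiotic list was called upward with a median below 0, and the mitochondrial, Wnt and JAK-STAT lists, which were not called, also had a median or mean of another sign than the test. The complement (adjusted p = 0.0573), NF-kB (0.0662) and endoplasmic reticulum (0.0791) lists did not pass (edgeR camera, Benjamini-Hochberg). With a library left out, the camera adjusted p of edgeR, with Benjamini-Hochberg adjustment, was 0.119 without Nkx castrate 1 and 0.461 without Nkx castrate 2 for the xenobiotic list, 0.00973 without Clu intact 1 for complement, 0.0445 without Nkx intact 2, 0.0156 without Nkx castrate 1, 0.00756 without Nkx castrate 2 and 0.0106 without Clu intact 1 for NF-kB and 0.00368 without Nkx intact 1 and 0.000409 without Clu intact 2 for the endoplasmic reticulum list. Cholesterol synthesis genes lower numbered 5 without Nkx intact 1, 1 without Nkx intact 2 or Clu intact 1 and 2 without Clu intact 2. Interferon genes higher numbered 0 without either Nkx intact library or Clu intact 2, 15 without Nkx castrate 1 and 14 without Nkx castrate 2, and cell cycle genes higher 1 without Nkx intact 1, 0 without Nkx intact 2 or either Clu intact library and 12 without either Nkx castrate library. Complement genes higher numbered 1 without either Nkx intact library, 9 without either Nkx castrate library and 3 without either Clu intact library, and lower 0 without either Nkx intact library or Clu intact 1, 5 without either Nkx castrate library and 1 without Clu intact 2. Wnt genes higher numbered 2 without either Nkx intact library and 3 without Clu intact 2, and lower 0 without either Nkx intact library or either Clu intact library and 8 without either Nkx castrate library. Xenobiotic genes lower numbered 0 without either Nkx intact library or either Clu intact library, and cholesterol synthesis genes higher 0 without either Nkx intact library or either Clu intact library and 2 without Nkx castrate 1. Calls were lost for Parp14 without either Nkx intact library or Clu intact 2, for Msmo1 without Nkx intact 2 or Clu intact 1, and for Mcm6 without Nkx intact 2 or either Clu intact library. They were also lost for Lbp without Nkx intact 2 and for Pigr without either Nkx intact library. In that order their adjusted p rose to up to 0.0841, 0.0697, 0.164, 0.0615 and 0.0825 (edgeR quasi-likelihood, Benjamini-Hochberg).

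In the comparison of Clu intact with Nkx castrate, population, mouse line and hormonal state differ together, and its fold changes are the difference of the other comparisons'. Secretory, proximal luminal, protein-folding and cell cycle genes were higher in Clu intact. Tgm4 averaged 4252 ± 1090 CPM (SD, n = 2) in Clu intact and 3.03 ± 1.67 CPM (SD, n = 2) in Nkx castrate, a log2 fold change of 10.42 (SE 0.38). Mmp7, a matrix metalloproteinase of glandular epithelia, was at 1131 ± 13.5 and 40.6 ± 16.2 CPM (log2 fold change 4.80, SE 0.26). Pbsn was 21-fold, Msmb 271-fold, C1rb 343-fold and Abcc4 9.71-fold higher, and Abo, with few counts in Nkx castrate, was higher by a ratio of 1005 (95% counting interval 278 to 8308). Clca1 was at least 866-fold higher and Camk2b at least 445-fold lower, each against 0 counts. Upk3a was 915-fold lower in Clu intact, Gdf15, a stress-induced cytokine, 53.1-fold lower and Sectm1b 59.3-fold lower. Of the 22 secretory markers, 15 were higher and 1 lower (16 and 1 when adjusted over the list alone), and of the 30 androgen response genes 11 and 6 (the same when adjusted over the list alone). Of the 26 folding genes 17 were higher and 1 lower (22 and 1 when adjusted over the list alone), and of the 25 cell cycle genes 13 and 0 (15 and 0 when adjusted over the list alone). Creld2 was 7.02-fold and Pdia4 5.54-fold higher. Mki67 was at 94.1 ± 36.4 against 4.14 ± 3.98 CPM (log2 fold change 4.47, and 6.13 without Nkx castrate 1 and 3.76 without Nkx castrate 2). For Tgm4, Mmp7, Creld2, Mki67 and Upk3a, edgeR's quasi-likelihood test gave Benjamini-Hochberg adjusted p-values of 0.000102, 0.000197, 0.000853, 0.00449 and 0.000338. Of 13846 genes, 1221 were higher and 1121 lower at an adjusted p under 0.05, of which 934 and 835 differed at least 2-fold, and 4495 genes had an unadjusted p under 0.05. The secretory markers and the androgen response genes had adjusted p = 1.46e-22 and 0.000323 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.095 and 0.095 with an estimated correlation. The folding genes and the cell cycle genes had adjusted p = 5.43e-14 and 7.87e-07 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.32 and 0.32 with an estimated correlation. Leaving out a library moved the fold of 7 of the 38 called genes named for this comparison over 1.5 times. The log2 fold change of Upk3a was -8.92 without Clu intact 2 and -14.06 without Clu intact 1, which leaves 0 counts in Clu intact, that of Tgm4 11.16 without Nkx castrate 1 and that of Msmb 7.49 without Nkx castrate 1 and 8.87 without Nkx castrate 2. The counts of genes were 913 higher and 735 lower without Nkx intact 1 and 867 and 739 without Nkx intact 2. They were 1888 and 1560 without Nkx castrate 1, 2010 and 1844 without Nkx castrate 2, 579 and 405 without Clu intact 1, and 417 and 270 without Clu intact 2. Cell cycle genes higher numbered 6 without either Nkx intact library or Clu intact 1 and 3 without Clu intact 2. Secretory markers lower numbered 2 without Clu intact 1. Androgen response genes higher numbered 7 without either Clu intact library, and lower 3 without Clu intact 1 and 2 without Clu intact 2. Their adjusted p was 0.239 without Nkx castrate 2 (edgeR camera, Benjamini-Hochberg).

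Proximal luminal genes were also higher in Clu intact than in Nkx castrate, and the xenobiotic list passed upward. Wfdc2 was at 499 ± 33.3 against 6.08 ± 0.816 CPM (SD, n = 2; log2 fold change 6.36, SE 0.18), and Ly6a, a surface antigen of progenitor cells, was 32.6-fold higher. Of the 24 proximal markers 12 were higher and 2 lower (13 and 4 when adjusted over the list alone). Of the 22 xenobiotic genes 6 were higher and 3 lower (8 and 4 when adjusted over the list alone), with Cbr2 15.8-fold, Gsta4 27.9-fold and Cyp2f2 15.9-fold higher. Urothelial markers went both ways, 5 higher and 4 lower of 13 (6 and 5 when adjusted over the list alone), with Gsdmc2 13.8-fold higher and Sprr1a 5.47-fold lower. Clu was 2.39-fold higher in Clu intact and Pgr was 40.6-fold lower (log2 fold change -6.07 without Clu intact 2). Of the 10 lineage genes and receptors 2 were higher and 2 lower (3 and 4 when adjusted over the list alone). For Wfdc2 and Clu, edgeR's quasi-likelihood test gave Benjamini-Hochberg adjusted p-values of 3.71e-05 and 0.00583. The proximal markers and the xenobiotic genes had adjusted p = 1.10e-17 and 9.57e-07 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.095 and 0.095 with an estimated correlation. The urothelial list, whose mean had another sign than the test, and the lineage list did not pass in edgeR's camera (Benjamini-Hochberg adjusted p = 0.73 and adjusted p = 0.35). Proximal markers lower numbered 1 without either Nkx intact library or Clu intact 1 and 4 without Nkx castrate 1. Xenobiotic genes higher numbered 10 without Nkx castrate 2, and lower 5 without Nkx castrate 1 and 1 without Clu intact 1. Urothelial markers higher numbered 2 without Clu intact 2, and lower 2 without Clu intact 2. Lineage genes called in this comparison and higher numbered 4 without Nkx castrate 2 and lower 4 without Nkx castrate 1.

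Immediate early and AP-1 genes were lower in Clu intact than in Nkx castrate, and the NF-kB, JAK-STAT, cholesterol synthesis and glucocorticoid lists passed downward. Egr1 was at 856 ± 45.7 against 6053 ± 213 CPM (SD, n = 2; log2 fold change -2.82, SE 0.18) and Fos at 836 ± 104 against 4601 ± 753 CPM. Of the 26 immediate early genes 17 were lower and 1 higher (18 and 1 when adjusted over the list alone), with Nr4a1 6.57-fold lower. Of the 12 AP-1 genes 10 were lower (the same when adjusted over the list alone), with Junb 5.86-fold and Atf3 4.04-fold lower. Lower members numbered 9 of 25 NF-kB genes, with Rela 2.39-fold lower, and 5 of 24 JAK-STAT genes beside 1 higher, with the kinase Pim1 10.8-fold and Socs2 3.94-fold lower. They numbered 9 of 21 cholesterol synthesis genes, with the squalene synthase gene Fdft1 3.04-fold lower, and 3 of 12 glucocorticoid-induced genes beside 2 higher, with Per1 6.59-fold lower and Fkbp5 22.6-fold higher. Adjusted over the list alone, these lower counts were 9, 9, 12 and 4. For Egr1, Fos, Rela, Pim1 and Fkbp5, edgeR's quasi-likelihood test gave Benjamini-Hochberg adjusted p-values of 0.000213, 0.000614, 0.00499, 0.00156 and 0.000529, and Rela lost its call without Clu intact 2 (0.0739). The immediate early list and the AP-1 family had adjusted p = 9.76e-21 and 7.70e-16 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.095 and 0.095 with an estimated correlation. The NF-kB list and the JAK-STAT list had adjusted p = 0.00804 and 0.0184 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.775 and 0.233 with an estimated correlation. The cholesterol list and the glucocorticoid list had adjusted p = 0.00063 and 0.0491 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.32 and 0.32 with an estimated correlation. Leaving out libraries ended these calls for NF-kB (0.31 without Nkx castrate 1), JAK-STAT (0.0688 without Nkx castrate 2) and the glucocorticoid list (0.0691 without Nkx intact 1, 0.0671 without Nkx intact 2, 0.0713 without Nkx castrate 1, 0.0533 without Nkx castrate 2, 0.144 without Clu intact 1 and 0.148 without Clu intact 2) as adjusted p of edgeR's camera with Benjamini-Hochberg adjustment. NF-kB genes lower numbered 3 without either Nkx intact library, 14 without Nkx castrate 2, 4 without Clu intact 1 and 0 without Clu intact 2, and JAK-STAT genes 8 without Nkx castrate 2 and 3 without either Clu intact library. JAK-STAT genes higher numbered 3 without Nkx castrate 1, 2 without Nkx castrate 2 and 0 without Clu intact 2, glucocorticoid-induced genes higher 1 without either Clu intact library and immediate early genes higher 2 without Nkx castrate 1. Cholesterol synthesis genes lower numbered 3 without either Clu intact library, and glucocorticoid-induced genes 5 without Nkx castrate 2.

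Marker lists of other cell types in this comparison depended on single libraries. Of the 19 leukocyte markers 6 were lower in Clu intact (13 when adjusted over the list alone), with Cd74 at 24.9 ± 2.29 against 169 ± 141 CPM (SD, n = 2). Of the 12 endothelial markers, Cldn5 was the 1 called higher, at 34.9 ± 21.1 against 1.7 ± 1.25 CPM (the same when adjusted over the list alone). Basal markers numbered 4 lower and none higher of 20 (7 and 3 when adjusted over the list alone). Stromal markers numbered 1 lower of 20 (the same when adjusted over the list alone) and red blood cell genes 1 lower of 4 (the same when adjusted over the list alone). None of 6 seminal vesicle genes, 14 mitochondrially encoded genes or 4 ionocyte or neuroendocrine markers was called by edgeR. At an unadjusted p under 0.05 there were 2 seminal vesicle and 4 mitochondrial genes higher and 1 ionocyte or neuroendocrine marker lower. DESeq2 called 2 mitochondrial genes higher and 1 ionocyte or neuroendocrine marker lower, and limma-voom 1 mitochondrial gene higher. The leukocyte markers and the endothelial markers had adjusted p = 0.000178 and 0.0184 in edgeR's camera (Benjamini-Hochberg), and adjusted p = 0.775 and 0.775 with an estimated correlation. The other lists named for this comparison here, and those left unnamed, did not pass, and the mean of the mitochondrial list had another sign than the test. In camera the leukocyte list no longer passed without Nkx castrate 1, and the endothelial list without Nkx castrate 2 or Clu intact 1. The stromal list passed without either castrate library, its called members mostly higher without Nkx castrate 1 and mostly lower without Nkx castrate 2. Lists that newly passed were basal without Nkx castrate 2, seminal vesicle without Clu intact 2, complement without Nkx castrate 1 and interferon without Clu intact 1. Leukocyte markers lower numbered 3 without Nkx intact 2, 16 without Nkx castrate 2 and 0 without either Clu intact library. Endothelial markers higher numbered 12 without Nkx castrate 1, 2 without Nkx castrate 2 and 0 without Clu intact 1. Stromal markers lower numbered 12 without Nkx castrate 2 and 0 without either Clu intact library and higher 8 without Nkx castrate 1 and 4 without Nkx castrate 2. Basal markers lower numbered 0 without either Nkx intact library or Clu intact 1, 9 without Nkx castrate 2 and 2 without Clu intact 2, and higher 4 without Nkx castrate 1 and 1 without Nkx castrate 2. Red blood cell genes lower numbered 0 without either Nkx intact library, Nkx castrate 2 or either Clu intact library. The log2 fold change of Cd74 was -2.77, and -1.48 without Nkx castrate 1 and -3.42 without Nkx castrate 2, and that of Cldn5 4.33, and 5.41 without Nkx castrate 1 and 3.56 without Clu intact 1. Cd74 lost its call without either Clu intact library (adjusted p up to 0.0763) and Cldn5 without Clu intact 1 (0.109) (edgeR quasi-likelihood, Benjamini-Hochberg).

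The Nkx castrate and Clu intact groups were both compared with the same Nkx intact libraries, and the genes called in both comparisons were counted. In the same direction were 363 genes, 193 higher in both, among them Atp10b, and 170 lower in both, among them Azgp1. In opposite directions were 61 genes, 38 of them lower in Nkx castrate and higher in Clu intact, such as Fkbp5 (168 ± 35.2 CPM in Nkx intact, 26.4 ± 10.1 CPM in Nkx castrate and 598 ± 234 CPM in Clu intact, SD, n = 2). The other 23 genes went the other way. All 61 were also called between Clu intact and Nkx castrate by edgeR, as were 69 of the 193 and 44 of the 170. Independent lists of these sizes would share 34.98 genes higher, 31.79 lower and 67.8 opposite. With no gene changed, 50 simulated draws against the same controls shared 0.06 and 0 on average, which cannot gauge lists of changed genes. The covariance of the log2 differences was 0.530 against 0.160 in the simulation, a difference of 0.371, and 0.394 and 0.355 with a single control library for each comparison. The correlation was 0.405 against 0.510 in the simulation. Splitting the 2 control libraries leaves 1 on each side, so part of the excess over independent lists may come from shared controls. The 363 became 61 without Nkx intact 1, 43 without Nkx intact 2, 943 without Nkx castrate 1, 833 without Nkx castrate 2, 138 without Clu intact 1 and 133 without Clu intact 2. The call of Fkbp5 (chosen after its values were seen) in Clu intact was lost without either Nkx intact library or Clu intact 2 (adjusted p up to 0.152), and in Nkx castrate without Nkx intact 1 (0.0514; edgeR quasi-likelihood, Benjamini-Hochberg).

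**Figure D3:**
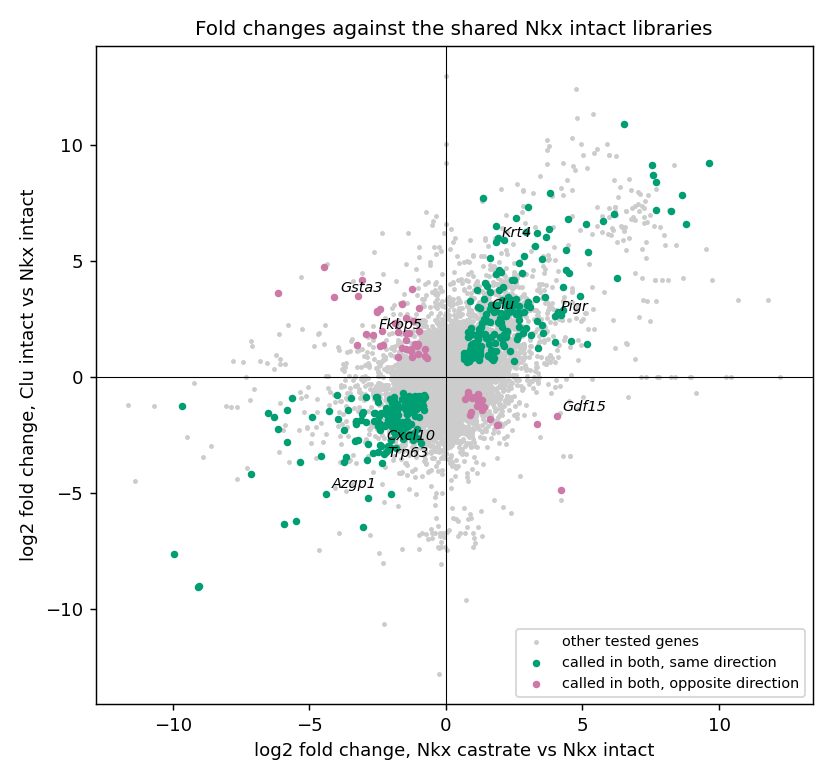
Each point is a tested gene, with the log2 fold change of Nkx castrate against Nkx intact on the x axis and of Clu intact against Nkx intact on the y axis, both relative to the same control libraries. Genes called in both are coloured, 363 in the same direction (green) and 61 in opposite directions (pink).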

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

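Leaving out libraries for the member counts of the lists, the families of genes and the genes chosen after their values were seen were tests chosen only after the results were seen. Under every alternative named here, 0 called genes were called in the opposite direction by edgeR, DESeq2 or limma-voom. Of the gene counts under an alternative, 51 stayed within 1.5 times the reported count and 45 did not. Scaling by DESeq2's or upper-quartile factors, leaving out mitochondrial and the 20 most abundant genes, a stricter filter, limma-voom and the replicate block (with the numbers' deviations correlated at 0.0901, 0.0437 and 0.234 between groups) were all among the 51, and the scalings moved the median of all genes by at most -0.0518 on the log2 scale. Without a filter, which tests more genes, 1197 genes were higher and 1103 lower in Nkx castrate against Nkx intact, 1467 and 1198 in Clu intact against Nkx intact, and 1736 lower in Clu intact against Nkx castrate. DESeq2 called 978 higher and 961 lower in Nkx castrate against Nkx intact, 1101 lower in Clu intact against Nkx intact and 1683 lower in Clu intact against Nkx castrate, and the cause was not tested. With only the groups compared, which leaves 2 residual degrees of freedom, 297 were higher and 374 lower in Nkx castrate against Nkx intact and 1761 and 1548 in Clu intact against Nkx intact.

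Leaving out a library leaves a group with 1, which is then assumed to vary like the others. Genes higher in Nkx castrate than in Nkx intact ranged from 72 (without Nkx intact 2) to 1220 (without Nkx castrate 2), and lower from 137 (without Nkx intact 2) to 1323 (without Nkx castrate 1). For Clu intact against Nkx intact the higher ranged from 214 (without Nkx intact 2) to 1790 (without Nkx castrate 1) and the lower from 157 (without Nkx intact 1) to 1561 (without Nkx castrate 1). For Clu intact against Nkx castrate the higher ranged from 417 (without Clu intact 2) to 2010 (without Nkx castrate 2) and the lower from 270 to 1844 (without the same libraries). The counts rose in all 3 comparisons without either castrate library, the pair that differed most (chi-square per degree of freedom 70.9, against 15.1 in Nkx intact and 17.1 in Clu intact). The 363 genes changed the same way in both comparisons with Nkx intact became 642 with DESeq2 and 43 (without Nkx intact 2) to 943 (without Nkx castrate 1), the cause not tested for the first.

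Lists called by camera numbered 0 in each comparison with an estimated correlation, and 8 and 8 with fry in the comparisons with Nkx intact, which asks another question. They stayed within 1.5 times under DESeq2's factors, the replicate block and each library left out. Of 1769 values of 137 gene results under an alternative, 1671 kept their direction and side of the threshold, 86 were no longer past it, 9 newly passed it and 3 reversed. The reversals were Pecam1 (-0.25), Vwf (-0.13) and Cd74 (-0.45) in Nkx castrate against Nkx intact without Nkx castrate 1, whose main values of 2.23, 1.92 and 0.83 had not passed and came from that library. Without Nkx castrate 2 all passed, with 3.085 for Pecam1 and 2.715 for Vwf. Leaving out the most abundant genes gives them no value. With 200 genes changed, fewer than called here, 12.5%, 11.6% and 9.46% of simulated 2-fold changes were called, so uncalled genes may have changed.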

Other observations

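The gene families, the genes named with them, and all weighing tests except those of heat shock genes and of further smooth muscle genes were chosen only after the results were seen.

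Among 23 gene families chosen after the values were seen, mucins, the glycoproteins of mucus and of apical surfaces, were higher in Clu intact. Muc20 averaged 0.586 ± 0.288 CPM in Nkx intact, 1.08 ± 0.0619 CPM in Nkx castrate and 35.6 ± 3.81 CPM in Clu intact (SD, n = 2), a log2 fold change of 5.90 (SE 0.45) against Nkx intact (6.51 without Nkx intact 2) and 5.03 (SE 0.39) against Nkx castrate. Of 6 mucins 5 were called higher against either Nkx group, but against Nkx intact only 1 without Nkx intact 1, Nkx intact 2, Clu intact 1 or Clu intact 2, and against Nkx castrate 3 without Nkx intact 2, 2 without Clu intact 1 and 1 without Clu intact 2. The adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.000512 for Muc20 against Nkx intact. For the family edgeR's camera gave Benjamini-Hochberg adjusted p = 0.000269 and 0.000405 over the 23 families, and adjusted p = 0.934 and 0.634 with an estimated correlation.

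Subunits of the COPI and COPII vesicle coats, which move cargo between the endoplasmic reticulum and the Golgi, were lower in Nkx castrate than in Nkx intact, with 5 of 20 called. Sec24d, a cargo adaptor of COPII, went from 159 ± 7.25 to 57.8 ± 0.668 CPM (SD, n = 2; log2 fold change -1.46, SE 0.16), and Copz2 had a log2 fold change of -1.78 (SE 0.26). Of 21 keratins 5 were called higher, among them Krt8 by 1.66 (SE 0.20) and Krt18 by 1.16 (SE 0.20) on the log2 scale. The adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.00242 for Sec24d, 0.00699 for Copz2, 0.00351 for Krt8 and 0.0125 for Krt18. Without Nkx intact 2 it was 0.0781 for Copz2, and without either Nkx intact library up to 0.0739 for Krt8 and 0.165 for Krt18. Coat genes called lower numbered 2 without Nkx intact 1, 1 without Nkx intact 2, 12 without Nkx castrate 2, 3 without Clu intact 1 and 3 without Clu intact 2, and keratins called higher numbered 1 without Nkx intact 1 and 2 without Nkx intact 2 and lower 5 without Nkx castrate 1. All these directions held under both other scalings. For the coats edgeR's camera gave Benjamini-Hochberg adjusted p = 5.41e-05 and for the keratins 0.00805, and adjusted p = 0.899 for each with an estimated correlation. Counts of mt-Co2 (10 to 26) and mt-Co3 (4 to 38) were far below those of mt-Co1 (17521 to 37864) in every library, so these mitochondrial genes carry little information in this file.

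Immediate early genes were lower in Clu intact than in Nkx intact. Stress from digestion stays open where it spares 12 heat shock genes outside the lists, whose median log2 difference was -0.0367 (SE 0.203 over genes). A lower share of basal cells stays open. In Nkx castrate, where castration differs, the 18 members lower in Clu intact had a median of 0.0711 (SE 0.184 over genes) against Nkx intact. Mouse line, reporter and sorting session stay open beside the population itself, since 0 populations were sorted from both of the 2 lines.

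Endothelial markers were higher in Clu intact, with 12 of 12 higher in Clu intact 1 than in Clu intact 2 (median log2 ratio 1.29, SD 0.17) and 12 of 12 in Nkx castrate 1 than in Nkx castrate 2 (2.64). This is consistent with a share of endothelial cells or their RNA that differs between libraries, which a sort on the marker would remove only if those cells lacked it. A lower share of epithelial cells that raises every other type alike stays open. Medians of co-varying genes (leukocyte -2.30, endothelial 3.60, SE of the difference 0.73) cannot settle it. A biological difference between the populations in the marked cells themselves was not tested and stays open.

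The smooth muscle genes Myh11 and Acta2 were higher in Nkx castrate, while the fibroblast and smooth muscle list did not pass. Of 10 further smooth muscle genes outside the lists, 5 were higher in both castrate libraries than in both Nkx intact libraries, among them Mylk (250.7 and 82.7 CPM, against 27.8 and 26.8 CPM). Smtn, Tpm2 and Synm were lower in Nkx castrate 2 (97.0, 56.3 and 19.5 CPM) than in both Nkx intact libraries. This leaves open whether smooth muscle cells or their RNA may be the source. A stromal mixture of fixed makeup stays open, as its test holds genes chosen as high. Medians of 5 smooth muscle and 14 fibroblast members were 4.06 and 1.10 in Nkx castrate 1 and 2.21 and -1.88 in Nkx castrate 2. They differed by 2.96 (SE 0.997 over genes) and 4.09 (SE 0.98) log2. Expression of these genes by the marked cells after castration, and a sort that let in other cells, both stay open.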
